A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

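RNA of Saccharomyces cerevisiae was compared on 4 spotted arrays, each hybridised with total RNA of wild-type cells labelled with Cy3 and total RNA of lpz8 null cells labelled with Cy5. The series title names Haa1, and lpz8 was read as HAA1 on that basis and on the values of the HAA1 spot. Per the labels, 2 arrays held null cells grown in low copper and 2 held null cells grown in high copper, and 1 array of each condition was marked as a repeat. The copper condition of the wild-type RNA, the copper concentrations and the separation of cultures were not stated in the labels. No array had the dyes exchanged, so a dye effect of a single gene could not be separated from the genotype.

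The deposited table held 1 log ratio per spot and array for 8832 spots. Its normalization by the authors, its log base and its direction were not given in the sources used here. The base was inferred from the values: among values beyond 2.9 in size, 29 of 111, 31 of 56, 22 of 56 and 25 of 59 on the 4 arrays lay within 0.0011 of the log2 of a whole ratio after 1 constant per array, against 14, 11, 9 and 7 for natural logs. Without that constant the counts were 1, 0, 0 and 25 for log2 against 4, 5, 0 and 0 for natural logs. The whole ratios tried reached further beyond 2.9 in log2 than in natural logs, which favours log2, and other bases were not tried. The deposited values were taken on this basis as log2 ratios to which a single constant per array had been added, a reading that stays an assumption. The direction was taken from the dyes, Cy5 over Cy3, and HAA1 lay far below 0 on each of the 3 arrays that measured it. Channel intensities, backgrounds and spot flags were not used here, so the signal above background behind each ratio was unknown, and the number of arrays limited the precision.

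The deposited medians were -0.15 and -0.067 for low copper replicates 1 and 2, -0.009 for high copper replicate 1 and 0 for high copper replicate 2. Values were missing for 17.9%, 5.42%, 4.79% and 5.82% of spots in the same order. Replicates were numbered in the order of the records, and low copper replicate 2 and high copper replicate 1 were the arrays marked as repeats. Of the spots, 6956 carried 1 gene name in the platform annotation, 0 carried several and 1876 carried none. The 6956 names were checked against the RefSeq gene table of assembly R64, which was used for names and neighbours alone. No coordinates were printed because the array's build was not given.

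Each array was centred on its median over the spots measured on all 4 arrays. Spots of a gene were averaged, and the 5137 genes measured on all 4 arrays were tested. Among them 805 genes had more than 1 spot, and the spot means of 20 (2.48%) lay over 1 log2 unit apart. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with a mean for each copper condition. The contrasts were the mean of both conditions against 0, each condition against 0, and high minus low copper. The fit had 2 residual and 2.22 prior degrees of freedom, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Genes with a log2 ratio of at least 1 in size and 1 sign on all 4 arrays were also counted without a test. Nothing in the labels placed the arrays of a condition in separate cultures, so p-values of single genes measured the spread between these arrays, which may be technical.

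Gene lists were fixed before the data were examined, 23 in all, of which 21 were tested with limma's camera at a preset correlation of 0.01 and adjusted over the lists within each contrast. At this preset camera takes the spread from the statistics of the genes, so its p-values do not measure replication between arrays or cultures. Camera with an estimated correlation and fry were run beside this setting. The estimated setting tests on the 2 residual degrees of freedom, so it has little power here. Over both conditions the estimate was 0.0039 for the respiration list and -0.249 for the Ace1 list, below the preset, and neither passed with it. Losing a call under this setting is therefore not by itself evidence of correlation between genes. For all other lists that camera called over both conditions, the estimate lay above the preset. It ran from 0.068 for phosphate to 0.706 for glycolysis, with 0.116 for ribosomal proteins and 0.169 for chaperones. For these lists the p-values at the preset may be too small. The genes named were set by a rule also fixed in advance: HAA1 and its neighbours and the Haa1, Ace1 and Mac1 lists; the 15 lowest and 10 highest means past the threshold with 1 sign on all 4 arrays; the 5 lowest and 5 highest of each copper condition; the 3 lowest and 3 highest differences between conditions where none passed; and the 2 to 4 members of every other list with the smallest p. Genes named outside this rule are said to have been chosen after their values were seen.

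The fits were tested on simulated data with 200 changed genes among 5137. The simulated noise was normal and independent, with 1 spread per gene shared by all 4 arrays and drawn from the fitted prior. The model's assumptions thus held by design, and the shares recovered need not hold for these arrays. Their median absolute deviations were 0.39 on low copper replicate 1 and 0.27 to 0.28 on the others. For both conditions together, 88% of genes changed by 1 log2 unit and 96% of those changed by 2 were recovered, with 8 unchanged genes among 192 calls. For low copper the recovered shares were 76% and 94%, for high copper 76% and 93%, and for high minus low copper 43% and 83%. A search for runs of displaced spots, in which each array's values were compared with those of the other 3 arrays at the same spot and at other spots, was tested on a copy of 1 array with a moved run and recovered 100% of its 504 spots.

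Alternatives fixed in advance were values without centring, arrays scaled to equal median absolute deviation, genes measured on at least 3 arrays, robust eBayes, separate spots, the repeat arrays as a block, each array left out, no copper term, each pair fitted alone, other fold limits and other list tests. Leaving out or moving back a displaced run of spots on 1 array was added after the data were examined. Figures were drawn with matplotlib 3.10.9.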

Results

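The data comprised 4 two-channel arrays that set RNA of lpz8 (HAA1) null yeast cells against RNA of wild-type cells, 2 with null cells in low copper and 2 with null cells in high copper. HAA1 encodes a transcription factor related to the copper-responsive activators Ace1 and Mac1. The labels and series title pose the question of which transcripts depend on this gene and whether copper alters that dependence. Values are log2 ratios of null over wild type, centred on each array's median, so a negative value is a lower level in null cells. The arrays held 7254 and 8353 values for low copper replicates 1 and 2 and 8409 and 8318 for high copper replicates 1 and 2. Across the 5137 genes tested, the Pearson correlation was 0.46 between the low copper arrays and 0.71 between the high copper arrays, and 0.31 to 0.48 between conditions. These correlations are across genes, which are not independent replicates.

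HAA1 itself was the most strongly lowered of its locus. Its log2 ratio was -7.35 on low copper replicate 2, -6.96 on high copper replicate 1 and -4.15 on high copper replicate 2, a mean of -6.15 ± 1.75 (SD, n = 3). No fold is given, because the signal of the deleted gene in the null channel may lie at background. It had no value on low copper replicate 1, and its adjusted p was 0.0462 in the limma fit over genes measured on at least 3 arrays. Its neighbours did not pass the threshold. ICL2 stood at -0.01 ± 0.27, RPA135 at -0.11 ± 0.05 and SUT2 at 0.28 ± 0.21 (SD, n = 4), with adjusted p of 0.962, 0.219 and 0.0641, and REC8 at -0.51 ± 0.08 (SD, n = 3) with 0.061 in the fit over at least 3 arrays.

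Over both copper conditions, the named genes tested on all 4 arrays that fell furthest in null cells, TDA6, TPO2 and YRO2, belonged to the literature list of Haa1-dependent genes. TDA6 fell 10.4-fold (-3.38 ± 0.67, SD, n = 4), TPO2, a plasma membrane transporter of polyamines, 9.49-fold (-3.25 ± 0.33), and YRO2, a membrane protein related to Hsp30, 7.79-fold (-2.96 ± 0.54). YGP1, a secreted glycoprotein, lay at -2.10 ± 0.07 and YLR297W at -2.07 ± 0.49, and their adjusted p-values of 0.00308 were the lowest of the comparison. Genes outside the Haa1 list fell as well, among them STP4 (-2.81 ± 0.995), NRE1 (-2.00 ± 0.16), INO1, the enzyme that makes inositol phosphate from glucose phosphate (-1.91 ± 0.63), DAN1, a cell wall mannoprotein (-1.88 ± 0.96), YDR222W (-1.80 ± 0.36), EFM6 (-1.75 ± 0.29), TOS3 (-1.67 ± 0.40), URA1 (-1.54 ± 0.22) and LYS2 (-1.49 ± 0.86). All of these were past the threshold, with adjusted p between 0.00308 and 0.0464, and were below 0 on all 4 arrays.

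The 3 genes past the threshold that rose most belonged to the phosphate regulon. SPL2, a regulator of phosphate transport, rose 6.25-fold (2.64 ± 0.47, SD, n = 4), the phosphate transporters PHO89 and PHO84 rose 4.88-fold (2.29 ± 0.48) and 4.36-fold (2.13 ± 0.45), and their adjusted p-values were 0.0103, 0.0176 and 0.0159. BTN2, which sorts misfolded proteins, stood at 2.05 ± 1.42, ATG41 at 1.76 ± 0.88, the zinc-regulated ZPS1 at 1.75 ± 0.69, YOL014W at 1.63 ± 0.39, the glucose transporter HXT2 at 1.43 ± 0.13, RGI1 at 1.43 ± 0.15 and RIP1, a subunit of the respiratory chain, at 1.41 ± 0.42. All were above 0 on all 4 arrays and past the threshold.

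In total 600 of 5137 genes passed the limma threshold over both conditions, 269 lower and 331 higher, and 571 of them had 1 sign on all 4 arrays. Without centring the split was 225 lower and 181 higher. At least a 2-fold change of 1 sign on all 4 arrays was seen for 17 lower and 10 higher genes. The count of 600 depended on which arrays entered the fit. It rose when either low copper array was left out and fell when either high copper array was. The count was 36 with the repeat arrays as a block and 292 without a copper term. With an array left out, the complete pair alone estimated the spread: the low copper pair without either high copper array, the high copper pair without either low copper array.

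Of the 15 genes of the literature Haa1 list, 9 fell in null cells and 0 rose, with 14 lower when adjusted over the list alone. The median was -1.40 and camera's adjusted p was 1.47e-09. It was 0.327 with an estimated correlation, a setting under which 0 of the 21 lists passed over both conditions. The list was drawn from publications on this factor, some of which used arrays of the same kind of null strain. Neither these counts nor camera's p-values for this list, here or within a copper condition, are therefore independent evidence of its direction. Besides the genes above, GRE1 (-1.47 ± 0.21, SD, n = 4), GPG1 (-0.77 ± 0.27), SUR2 (-0.70 ± 0.27) and HRK1 (-0.47 ± 0.18) passed the threshold. SPI1, INM1 and HSP26 stood at -0.38, -0.19 and 0.07 and did not. PHM8 (-2.06 ± 1.16), TPO3 (-1.40 ± 0.81) and COM2 (-1.19 ± 0.64) missed the threshold with adjusted p of 0.0515, 0.0679 and 0.0627. Their values on high copper replicate 1 lay between -0.33 and -0.30, while on the other 3 arrays they lay between -2.77 and -1.23.

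**Figure D1:**
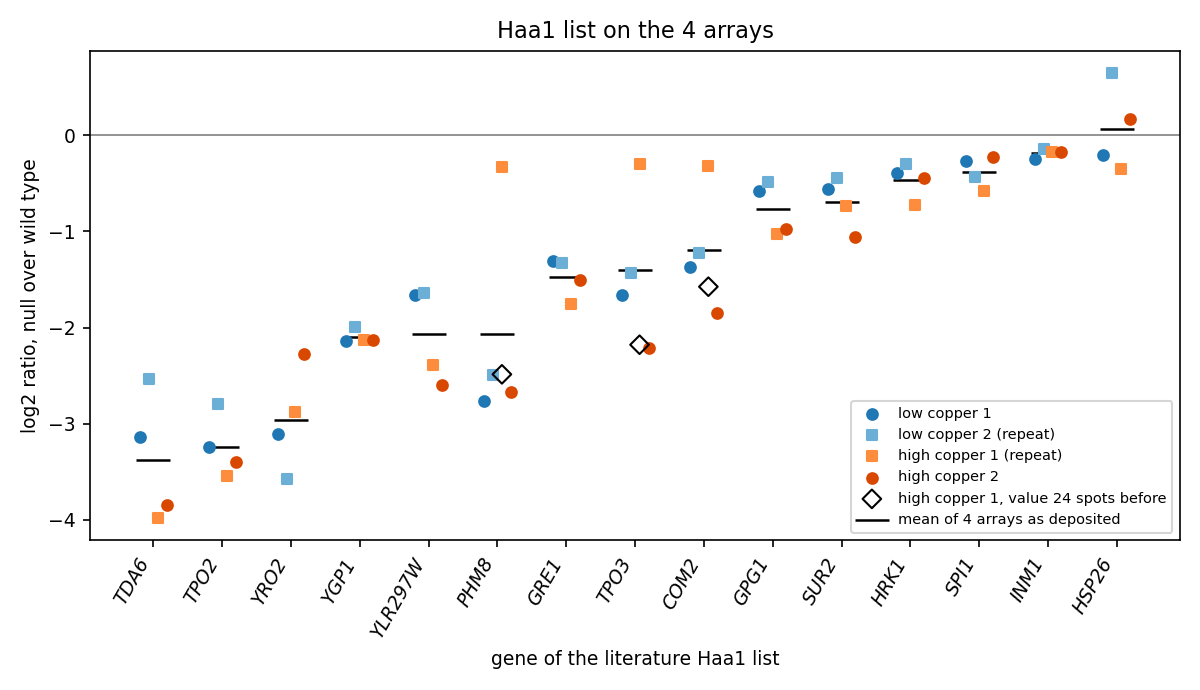
Log2 ratio of null over wild type (vertical axis) for the 15 genes of the literature Haa1 list on each of the 4 arrays, with the mean as a bar and, for 3 genes, the value found 24 spots earlier on high copper replicate 1 as an open diamond. TPO2 lies between -3.55 and -2.79 on all 4 arrays, while PHM8, TPO3 and COM2 lie near 0 on high copper replicate 1 alone and their diamonds lie at -2.49, -2.18 and -1.57.

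Those 3 genes were spotted in a run whose values on that array did not match their positions. Over 528 spots, numbers 1657 to 2184, the Spearman correlation of high copper replicate 1 with the mean of the other arrays was -0.015 at the same spot and 0.57 at the spot 24 places on, against 0.58 at the same spot over the rest of the array. The run and the 24 spots after it touched 320 tested genes. With its values moved back by 24 spots, PHM8 stood at -2.60, TPO3 at -1.87 and COM2 at -1.51 over the 4 arrays, with adjusted p of 0.00188, 0.00224 and 0.00446, and 751 genes passed the threshold, 334 lower and 417 higher. This setting was added after the data were examined, and all other values are those of the table as deposited.

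**Figure D2:**
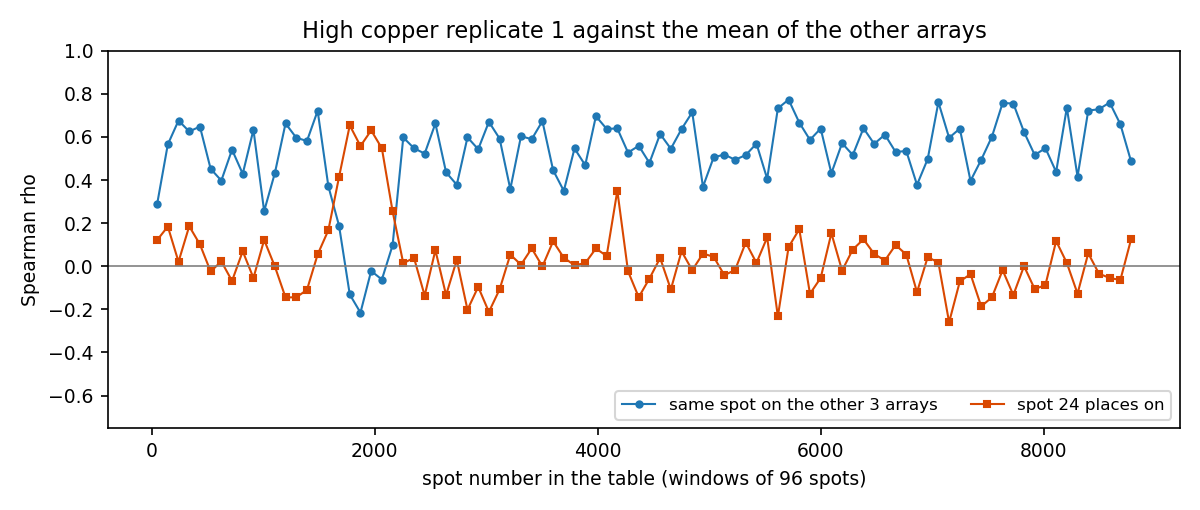
Spearman correlation (vertical axis) of high copper replicate 1 with the mean of the other 3 arrays, in consecutive windows of 96 spots along the table (horizontal axis, spot number), at the same spot (circles) and at the spot 24 places on (squares). The curves cross between spots 1657 and 2184, where the correlation over the run was -0.015 at the same spot and 0.57 at the spot 24 places on.

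Of the 4 copper detoxification genes driven by Ace1, 3 rose, and 2 of these are near-identical copies that cannot count as separate measurements. CUP1-1 and CUP1-2, the copies that encode the metallothionein Cup1, stood at 0.71 ± 0.12 and 0.66 ± 0.08 (SD, n = 4), or 1.64-fold and 1.58-fold higher, and SOD1 at 0.45 ± 0.14, while CRS5 stood at -0.01 ± 0.35. The count was also 3 adjusted over the list alone, and camera's adjusted p was 0.0121 (adjusted p = 0.367 with an estimated correlation). In low copper alone 0 of the 4 genes passed, 3 higher and 1 lower adjusted over the list alone, with a camera adjusted p of 0.0842. CUP1-1 and CUP1-2 stood at 0.62 and 0.61 there. In high copper 2 were higher, 4 adjusted over the list alone, with 0.000882 (adjusted p = 0.35 with an estimated correlation). The list's difference between high and low copper did not pass (camera adjusted p = 0.138). The Mac1 copper uptake list had 1 of 5 genes lower, IRC7 at -0.51 ± 0.26, and an adjusted p of 0.736. CTR1, the high-affinity copper transporter, stood at 0.06 ± 0.29 and FRE1 at 0.05 ± 0.18, and CTR3 (-0.55 ± 0.68) and REE1 (0.15 ± 0.25) did not pass. FRE7 had values on 3 arrays, with a mean of -0.39 ± 0.16 (SD, n = 3).

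Phosphate genes rose as a group over both conditions, and chaperone genes did so with lower ratios in low than in high copper. Of 15 phosphate regulon genes 10 rose and 13 rose when adjusted over the list alone, with 1 lower. The lower one was PHM8, which is also in the Haa1 list and lies in the displaced run. The median was 0.95 and camera's adjusted p 2.86e-08 (adjusted p = 0.327 with an estimated correlation). The acid phosphatases PHO11 and PHO5 stood at 1.22 ± 0.12 and 0.98 ± 0.13 (SD, n = 4) and the polyphosphate polymerase subunit VTC1 at 1.27 ± 0.26. Of 18 chaperone genes under the heat shock factor 13 rose, 16 adjusted over the list alone, with a median of 0.53 and an adjusted p of 1.97e-09 (adjusted p = 0.367 with an estimated correlation). FES1, SSA4 and HSP104 stood at 1.29 ± 0.67, 0.67 ± 0.74 and 0.75 ± 0.58. In low copper alone 0 of the 18 chaperone genes passed, 3 adjusted over the list alone, SSA4 standing at 0.03. Camera still called the list higher there (adjusted p = 0.0164, and 0.57 with an estimated correlation). In high copper 9 rose, 16 adjusted over the list alone. Of 30 genes listed for general stress and Msn2 and Msn4, 9 rose and 5 fell (16 and 7 adjusted over the list alone). HSP42 at 1.17 ± 0.49 and HSP30 at -1.19 ± 0.57 were among them, with a camera adjusted p of 0.00431 (adjusted p = 0.444 with an estimated correlation). SSA4 and HSP104 are in both this list and the chaperone list, so these calls are not separate. HSP26 and SPI1 are also in the Haa1 list. With genes of the Haa1 list left out of the others, 11 lists were still called over both conditions.

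Genes of the translation machinery moved in opposite directions. Of 132 ribosomal protein genes 31 rose and 1, RPL31B, had a lower mean (68 and 2 adjusted over the list alone). RPL31B stood at -2.75 in low and at 0.10 in high copper. The list median was 0.25 and camera's adjusted p 1.29e-14 (adjusted p = 0.367 with an estimated correlation). In low copper alone 0 rose and 1 fell, 65 and 2 adjusted over the list alone (camera adjusted p = 1.17e-18, and 0.35 with an estimated correlation). In high copper 0 passed, also over the list alone (1.24e-05 and 0.47). Of 38 ribosome biogenesis genes 10 fell, 20 adjusted over the list alone, among them NOP2 (-0.43 ± 0.49, SD, n = 4) and UTP5 (-0.42 ± 0.05), with a median of -0.28 and an adjusted p of 6.46e-08 (adjusted p = 0.371 with an estimated correlation). NOP2 stood at -0.04 and 0.04 on the low copper arrays and at -0.82 and -0.89 on the high copper arrays. Both medians had the signs given on each of the 4 arrays, and the shift of low copper replicate 1 by centring, from a median of -0.157 over these spots, did not alter them.

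Camera called smaller shifts in 4 further lists, of which fry did not call cell wall (fry adjusted p = 0.0685) or glycolysis (0.303). Of 37 genes of respiration and the TCA cycle 4 rose, also 4 adjusted over the list alone, with RIP1 and CYC1 (0.53 ± 0.38, SD, n = 4) among them and an adjusted p of 1.68e-06 (adjusted p = 0.327 with an estimated correlation). Of 21 iron uptake genes under Aft1 and Aft2, 6 rose, 7 adjusted over the list alone, among them the cell wall mannoprotein FIT2 (1.27 ± 1.30) and FET3 (0.62 ± 0.47), with an adjusted p of 0.00524 (adjusted p = 0.444 with an estimated correlation). In low copper alone this list had 0 of 21 genes past the threshold, a median of 0.02 and an adjusted p of 0.964, with FIT2 at 0.16. Of 21 cell wall genes 7 rose and 2 fell, 7 and 3 adjusted over the list alone, TIP1 (1.003 ± 0.467) and CCW12 (0.70 ± 0.32) among the higher, with an adjusted p of 0.026 (adjusted p = 0.503 with an estimated correlation). In high copper alone the cell wall median was 0.01 with an adjusted p of 0.693. Of 17 glycolysis genes 2 rose, GPM1 (0.32 ± 0.09) and CDC19 (0.39 ± 0.16), also 2 adjusted over the list alone, with an adjusted p of 0.047 (adjusted p = 0.693 with an estimated correlation) and of 0.219 in high copper alone. The glycolysis median did not keep 1 sign. It was 0.36 and -0.06 on low copper replicates 1 and 2, and -0.01 and 0.09 on high copper replicates 1 and 2.

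Over both conditions no shift passed the camera test in the remaining lists. Fry did call the drug resistance, sulfur, Yap1 and pheromone lists among them, with fry adjusted p of 0.00771, 0.0143, 0.03 and 0.0431. The p-values below are camera's. The zinc response list had 2 of 11 genes higher (3 adjusted over the list alone), ZPS1 and ZRT1 (1.17 ± 0.40, SD, n = 4), with an adjusted p of 0.145. The sulfur amino acid list had 4 of 23 higher (6 adjusted over the list alone), MET17 at 0.61 ± 0.50 among them, with 0.0668. In low copper alone the sulfur list had 1 of 23 genes higher, 10 adjusted over the list alone, and an adjusted p of 0.00796 (adjusted p = 0.35 with an estimated correlation), and in high copper 0 and 0.739. The drug resistance list of Pdr1 and Pdr3 had 2 of 11 lower (2 adjusted over the list alone), GRE2 (-0.78 ± 0.17) and RSB1 (-0.41 ± 0.31), with 0.0525. The hexose transport list had HXT2 higher and HXT1 (-1.14 ± 0.17), HXT5 (-0.65 ± 0.48) and HXT3 (-0.78 ± 0.51) lower among 9 genes, 3 and 4 adjusted over the list alone, with 0.73. The Gcn4 list had 4 of 26 higher (9 higher and 2 lower adjusted over the list alone) with 0.165, the Yap1 list TSA1 (0.41 ± 0.13) higher and GLR1 (-0.37 ± 0.29) lower of 14 (1 and 3 adjusted over the list alone) with 0.403. The ergosterol list had HMG2 (0.35 ± 0.15) higher and ERG11 (-0.47 ± 0.21) lower of 23 (1 and 3 adjusted over the list alone) with 0.0551. The pheromone response list had PRM5 (0.91 ± 0.18) higher and 3 lower of 12 (2 and 3 adjusted over the list alone), FUS1 (-0.44 ± 0.19) among the lower, with 0.165. The mating-type list had MF(ALPHA)1 (0.36 ± 0.20) higher of 6 (1 higher and 1 lower adjusted over the list alone), with 0.859. Median, mean and test differed in sign for the Mac1, hexose transport and mating-type lists.

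**Figure D3:**
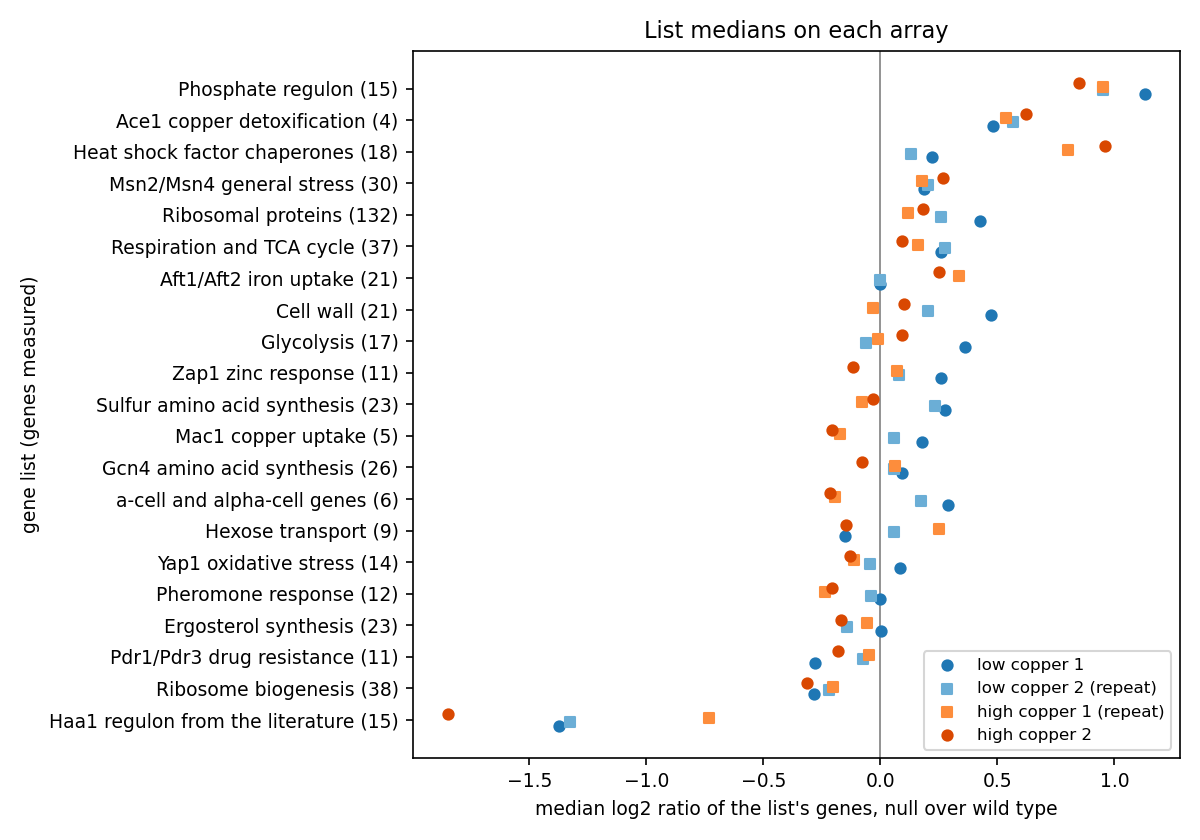
Median log2 ratio of null over wild type (horizontal axis) of the genes of each of the 21 tested lists on each of the 4 arrays, with the number of genes measured in parentheses. The chaperone medians lie at 0.22 and 0.13 on the low copper arrays and at 0.80 and 0.96 on the high copper arrays, while the phosphate medians lie between 0.85 and 1.13 on all 4.

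Marker genes of laboratory strains were described without a list test. URA3, whose spot lies in the displaced run, stood at 2.98, 1.83 and 2.28 on 3 arrays and at 0.18 on high copper replicate 1, with an adjusted p of 0.0634, and of 0.016 with the run moved back. LYS2 fell and MET17 rose, as given above, and LEU2 (-0.04 ± 0.40, SD, n = 4) did not pass. The other markers of the list, HIS3, TRP1 and ADE2, chosen for naming after their values were seen, stood at -0.02, 0.00 and 0.05.

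Among genes past the threshold in low copper, the largest falls were in YRO2 (-3.35 ± 0.33, SD, n = 2), TPO2 (-3.02 ± 0.32), TDA6 (-2.84 ± 0.43), the ribosomal protein gene RPL31B (-2.75 ± 0.17) and NRE1 (-2.14 ± 0.07). The largest rises among them were in SPL2 (2.88 ± 0.66), ZPS1 (2.31 ± 0.36), the zinc transporter gene ZRT1 (1.47 ± 0.32), VTC1 (1.47 ± 0.20) and HXT2 (1.40 ± 0.05). In all 34 genes passed the threshold, 22 lower and 12 higher, and 1569 had an unadjusted p under 0.05. Camera called 8 lists higher and 2 lower of 21, with adjusted p of 0.35 to 0.765 for those 10 with an estimated correlation; the Haa1 list (6 of 15 lower, 13 adjusted over the list alone, adjusted p = 2.14e-08) and the phosphate list (4 of 15 higher, 12 adjusted over the list alone, 2.91e-07) were among them. The count of 34 was 101 without low copper replicate 1, 1438 without low copper replicate 2, 0 without either high copper array, 0 with the repeat arrays as a block and 0 from the low copper pair alone. Without centring 17 genes were lower and 2 higher, with arrays scaled to equal spread 30 and 31, with separate spots 7 spots passed, and with the displaced run moved back 63 genes did.

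Among genes past the threshold in high copper, TDA6 (-3.92 ± 0.09, SD, n = 2), TPO2 (-3.47 ± 0.10), DAN1 (-2.69 ± 0.31), YRO2 (-2.58 ± 0.42) and YLR297W (-2.49 ± 0.15) fell furthest. BTN2 (3.28 ± 0.08), ATG41 (2.46 ± 0.36), SPL2 (2.41 ± 0.15), FIT2 (2.39 ± 0.32) and PHO89 (2.13 ± 0.31) rose furthest among them. In all 132 genes passed, 77 lower and 55 higher, and 1263 had an unadjusted p under 0.05. Camera called 7 lists higher and 2 lower of 21, with adjusted p of 0.35 to 0.484 for those 9 with an estimated correlation; the chaperone list had 9 of 18 genes higher, 16 adjusted over the list alone (median 0.84, adjusted p = 5.18e-14), and the iron list 3 of 21, 9 adjusted over the list alone (median 0.25, 7.81e-06). The lists of genes called in low and in high copper shared 18 lower and 7 higher genes and none in opposite directions, where independent lists of these sizes would share 0.330 and 0.128, a figure that leaves out the spread shared by both tests. The count of 132 was 898 without either low copper array or from the high copper pair alone, 0 without either high copper array and 0 with the repeat arrays as a block, and it was 363 with scaled arrays, 78 over genes on at least 3 arrays, 61 with separate spots and 201 with the displaced run moved back.

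Between the copper conditions, chaperone genes had the largest median difference of the 7 lists called. The labels do not give the copper condition of the wild-type RNA, so a difference between conditions is one of ratios and need not be a change in the effect of the deletion. The chaperone median log2 ratio was 0.25 in low and 0.84 in high copper, all 18 had a higher ratio in high copper, and the median difference was 0.75 (camera adjusted p = 4.73e-11; adjusted p = 0.421 with an estimated correlation). With the list alone adjusted, 13 of the 18 passed, among them SSA4 with a difference of 1.28 and FES1 with 1.15. The iron uptake list was also higher in high copper (median difference 0.27, adjusted p = 6.14e-05), TIS11 differing by 1.70 and FIT2 by 2.23. The ribosomal protein (median difference -0.20, adjusted p = 6.68e-08), cell wall (-0.40, 0.000402), sulfur (-0.22, 0.00145), respiration (-0.12, 0.00313) and pheromone (-0.17, 0.0424) lists were lower. Each of the 7 had an adjusted p = 0.421 with an estimated correlation.

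For single genes the difference passed the limma threshold for 0 of 5137, while 792 had an unadjusted p under 0.05 and the lowest adjusted p was 0.0564. That value was shared by BTN2, with a difference of 2.46 ± 0.11 (SE), and RPL31B, with 2.86 ± 0.14 (SE), which stood at -2.87 and -2.63 in low and at 0.03 and 0.18 in high copper. ARG3, an enzyme of arginine synthesis, differed by -2.64, PRE6 by -2.73 and RET2 by -2.15, and VLD1 by 2.85 and VAC8 by 2.51, and none passed. PRE6 and 1 of the 2 spots of RET2 lie in the displaced run, and VLD1 and VAC8 were far below 0 on low copper replicate 1 alone, at -5.16 and -4.40. With robust eBayes and with the displaced run moved back 2 genes passed, BTN2 and RPL31B, with adjusted p of 0.0397 and 0.0443. Without low copper replicate 1 the count was 22 and without low copper replicate 2 it was 743.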

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

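All of the tests of explanations in this part were chosen after the result they bear on was seen, and the settings that leave out or move the displaced run were added after the data were examined. The list tests between copper conditions were planned.

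The difference between the copper conditions drew attention to 7 gene lists, because camera found their null over wild-type ratios to differ between high and low copper. The median of high minus low was 0.75 for chaperones under the heat shock factor and 0.27 for iron uptake genes under Aft1 and Aft2. It was -0.22 for sulfur amino acid synthesis, -0.12 for respiration and the TCA cycle, -0.20 for ribosomal proteins, -0.40 for cell wall genes and -0.17 for the pheromone response. Each of the 7 had an adjusted p = 0.421 with an estimated correlation, and fry called 1 of them, sulfur amino acid synthesis.

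The chaperone difference was weighed further. A dye effect of each gene that is the same on all 4 arrays cancels in this difference by design, and one that differs between arrays was not tested. A difference between the repeat arrays and the others that is the same in both conditions also cancels by design, because each condition held 1 of each. One that differs between conditions was not tested. The median of high minus low was 0.80 within the arrays not marked as repeats and 0.56 within the repeats, each from 1 array against 1, so it was above 0 in both sets. What stays open is copper, acting on the effect of the deletion or, as the copper condition of the wild-type RNA is not given, on the null cells as such, and any other difference between the cultures of the conditions. The labels name no cultures, so these possibilities cannot be told apart. The list's adjusted p of 0.421 with an estimated correlation, tested on 2 residual degrees of freedom, does not decide between them.

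The weak values of TPO3, PHM8, COM2 and URA3 on high copper replicate 1 alone were weighed next: their mean absolute log2 ratio was 0.28 there and 2.25 on the other high copper array. Over 520 spots of the run, without those of the 4 genes, the Spearman correlation of the 2 high copper arrays was -0.0031 at the same spot and 0.65 at the spot 24 places on, against 0.71 at the same spot over the rest of the array. An effect of high copper on the spots of this run, which both arrays would share at the same spot, is argued against by these values, although the run was located from its distance to the mean of the other 3 arrays. Values stored 24 spots from their own position remain as the candidate explanation, with correlations to the mean of those 3 arrays of 0.56 at the spot 24 places on and -0.03 at the same spot. With the run moved back the mean absolute log2 ratio of the 4 genes on that array was 2.07.

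URA3 was higher and URA1 lower in null cells. The hypothesis that URA3 served as the disruption marker in a strain lacking it would lower the other targets of the pyrimidine regulator Ppr1, and of these URA4 stood at -0.99 with an adjusted p of 0.0198 while URA10 stood at 0.05 with 0.663, so the hypothesis stays open. URA2, URA5, URA6 and URA8 had a mean of 0.23 ± 0.20 (SD over the 4 genes). PPR1 itself stood at -3.31 on low copper replicate 1 and between -0.54 and -0.37 on the other 3 arrays, with an adjusted p of 0.187. A dye effect of these genes cannot be told apart from the genotype, because 0 arrays had the dyes exchanged, and the labels give no strain background.

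Spots with no gene name were examined outside the comparisons. Of 914 such spots measured on all 4 arrays, 92 passed the threshold over both conditions, 23 lower and 69 higher. This share is no higher than that of the named genes, 600 of 5137. Spot 2762 was at least 2-fold lower on all 4 arrays, with a mean of -4.11, and 3 unnamed spots were at least 2-fold higher. Of these 3, spot 8685 did not pass the threshold (limma adjusted p = 0.0509).

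Regroupings of the arrays were too few for a share under 0.05. Over both conditions 1 of 8 sign patterns of the 4 arrays, the real one, gave as many as 600 genes past the threshold, and the highest of the others gave 0. For high minus low copper 1 of the 3 splits into 2 and 2, the real one, gave as many as 792 genes with an unadjusted p under 0.05, and the highest of the others gave 74, which was the split of repeat arrays against the rest.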

How the results depend on the processing

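Leaving out or moving back the displaced run was added after the data were examined, and the other settings were planned. Directions were compared for named genes over both conditions, for the differences named by the rule, and for lists over both conditions and for the difference. No such call reversed in the settings compared, while some genes not past the threshold, such as ICL2, CRS5 and PRE6, changed sign. Named genes were not compared with separate spots or each pair alone. Lists were not compared without centring, with scaled arrays, over genes on at least 3 arrays or with robust eBayes. Calls within 1 copper condition were not compared. The balance of lower and higher genes did reverse: over both conditions it was 269 to 331, but 225 to 181 without centring, 1137 to 803 without low copper replicate 2 and 24 to 12 with the repeat arrays as a block. In low copper 22 to 12 became 30 to 31 with scaled arrays and 49 to 52 without low copper replicate 1, and in high copper 77 to 55 became 29 to 32 with separate spots. Calls of single genes were sensitive to which arrays estimated the spread. With a high copper array left out, the low copper pair alone estimated it, and with a low copper array left out, the high copper pair did. The number of arrays was the same in each case, so it does not account for the range of counts. Across genes the low copper pair correlated at 0.46 and the high copper pair at 0.71, and why the pairs differ was not tested. Over both conditions the count of 600 ran from 0 to 1940 with 1 array left out (0 without either high copper array, 959 without low copper replicate 1, 1940 without low copper replicate 2), and was 292 without a copper term. In low copper the count of 34 ran from 0 to 1438, and in high copper the count of 132 from 0 to 898, with an array left out. For high minus low copper the count of 0 ran from 0 to 743. With 1 array left in a condition, that array is assumed to vary like the other pair. Beside the counts of 0 without high copper replicates 1 and 2, limma gave 907 and 846 genes at an unadjusted p under 0.05 over both conditions, 942 and 942 for low copper and 445 and 400 for high copper. The low copper count was 19 without centring, 61 with scaled arrays, 7 with separate spots, 63 with the run moved back and 0 from its own pair alone, where 942 genes had an unadjusted p under 0.05. The high copper count was 363 with scaled arrays, 78 over genes on at least 3 arrays, 61 with separate spots, 201 with the run moved back and 898 from its own pair alone. The difference count was 2 with robust eBayes and 2 with the run moved back. With the displaced run left out, the counts were 648, 38, 144 and 0.

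The repeat label did not pair the arrays: the deviations of repeats and others correlated across genes at r = 0.087 over 2 pairs. With the repeat arrays as a replicate block the counts were 36 over both conditions, 0 in low copper, 0 in high copper and 0 for the difference, with 1773, 1520, 1158 and 713 genes at an unadjusted p under 0.05, on 1 residual degree of freedom fewer. The list calls under this block were 11 over both conditions and 6 for the difference.

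Genes changed at least 2-fold on all 4 arrays numbered 27, from 28 to 37 on 3 arrays, 77 at 1.5-fold and 8 at 3-fold. List calls over both conditions numbered 11, from 10 to 13 with an array left out, 0 with an estimated correlation, 13 with fry, 11 with the displaced run left out and 13 with it moved back. List calls for the difference numbered 7, from 6 to 10 with an array left out, 0 with an estimated correlation, 1, sulfur amino acid synthesis, with fry, and 10 with the displaced run either left out or moved back. The Haa1 list missed the threshold for the difference at an adjusted p of 0.0617 and passed it at 0.00276 with the run moved back, with a range of 0.0112 to 0.502 with an array left out. Fry's list calls over both conditions left out cell wall and glycolysis, which camera called, and added the drug resistance, sulfur, Yap1 and pheromone lists. The mean of HAA1 ran from -7.15 to -5.55 with an array left out. Signal over background was not used here, so its limit on dim spots is unknown.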

Other observations

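The groups and genes given here were chosen after their values were seen, and no list test was run on them. Relatives of YRO2 fell in null cells with it: MRH1, its paralog, stood at -0.85 and HSP30 at -1.19, with adjusted p of 0.0096 and 0.0059, below 0 on all 4 arrays. Besides DAN1, the mannoprotein genes TIR3 (-0.74), TIR2 (-0.74) and TIR4 (-0.67) fell, with adjusted p of 0.0223, 0.0274 and 0.0381, while TIR1 (-0.44, adjusted p 0.0608) and DAN4 (-0.54, adjusted p 0.0673) did not pass. The 22 PAU genes are of a family of closely related copies, so counts over them are not counts of separate measurements, although PAU3, PAU7, PAU17 and PAU23 had values unlike most others. Of the 22, 3 were below 0 in low and 21 in high copper, a difference not tested as a group. Only 2 of them, PAU2 and PAU22, passed the limma threshold in high copper, with adjusted p of 0.0419 and 0.0406. Over both conditions PAU2, PAU22 and PAU23 passed, with 0.0483, 0.0417 and 0.0288. Their median was 0.41 and 0.11 on the low copper arrays and -0.61 and -0.47 on the high copper arrays. Among 10 genes of inositol and phospholipid synthesis, INO1 and the inositol transporter gene ITR1 (-0.44, adjusted p 0.0267) fell and the other 8 did not pass. Of 32 genes of the proteasome and its regulator RPN4, 4 rose and 0 fell, with a median of 0.13, beside a median of 0.53 for the chaperones.

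Of the genes changed at least 2-fold on all 4 arrays, 4 lower and 1 higher are not named elsewhere. The lower ones were MDH2, a cytosolic malate dehydrogenase (-1.47), NQM1 (-1.39), AST1 (-1.31) and the phospholipase gene PLB3 (-1.23). NHP2, a protein of small nucleolar particles, was the higher one (1.36). Their adjusted p-values lay between 0.00586 and 0.0159.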
